A study of Mus musculus with 24 samples.

How the data were processed

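ATAC-seq, in which the Tn5 transposase cuts and tags DNA that is not wrapped tightly in nucleosomes, was applied to neuronal nuclei from mouse striatum. Per the labels' protocols, striata of 12-month-old C57BL/6 mice were dissected and frozen, nuclei were stained with an antibody to NeuN (a protein of most neuronal nuclei), NeuN-positive nuclei were collected by flow cytometry, and equal numbers of nuclei were transposed and made into libraries with a Nextera kit. There were 24 libraries from 4 genotypes, with 3 female and 3 male animals per genotype. WT denotes wild type. Q140 denotes animals heterozygous for a knock-in of Htt, the huntingtin gene, in which the CAG repeat is expanded. Msh3KO denotes animals lacking Msh3, a DNA mismatch repair gene, and Q140_Msh3KO denotes animals with both alleles. Libraries are named by sex and replicate number within a genotype, such as Q140 F2.

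The authors deposited 1 table of 147020 peaks with raw read counts per peak and library. Per the submitters' processing notes, BWA, SAMtools, Picard, MACS2 and featureCounts were used on build GRCm38. Their versions, order and settings are not given in the sources used here. Per the file name, the peaks came from combined data, so 1 set of peaks served all libraries and a region open in a single genotype can be missed or diluted. How reads were filtered, whether cut sites were shifted for the 2 strands of the transposase cut, and how duplicates were treated are not given in the sources used here. Per the file headers, each peak carries its position, the distance in bases to the nearest annotated transcription start, an annotated class and a gene symbol. The peaks did not overlap, had a median width of 396 bases and spanned 200 to 5763 bases. A gene symbol was missing for 281 peaks. The numbering of the peaks skips 1 number, and that peak was not analysed here. A peak is named below by the gene with the nearest annotated start, which need not be the gene it regulates. All 24 count columns were used, and 0 other columns held values of samples.

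Total deposited counts per library ran from 4372251 to 11736557, and the median tested peak held 28 counts per library. These are reads within peaks, so the share of each library outside peaks is unknown here. The counts of every pair of libraries of 1 genotype differed by more than sampling noise (chi-square per peak 1.33 to 8.80 over 60 pairs), and 0 pairs were identical.

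Counts were tested with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM, and filterByExpr with a count minimum of 10 kept 146155 peaks. A quasi-likelihood model with robust estimation was fitted to all 24 libraries with genotype and sex as terms. Genotypes were compared by contrasts, and p-values were adjusted by the Benjamini-Hochberg method over all tested peaks at 0.05. Fold changes are log2 values with an SE taken from the fold change and the square root of the F statistic. The interaction is the Q140 effect without Msh3 minus the Q140 effect with Msh3. The Q140 effect by sex came from a model with genotype by sex terms. CPM values are counts scaled to the TMM library size, given as mean ± SD over 6 animals.

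Peaks within 20 Mb of Htt and Msh3 were counted apart, because a targeted allele made in cells of another strain can carry flanking DNA of that strain. Peak classes were compared with Fisher's exact test against all tested peaks, and shares near the targeted genes against other autosomal peaks. Fisher's test treats peaks as independent, which neighbouring peaks need not be, so its p-values are descriptive. The share of the Q140 effect kept without Msh3 was measured with a score per animal. In each sex, the 500 higher and 500 lower peaks of smallest p for Q140 against WT were chosen, outside these windows and outside X and Y. In animals of the other sex, the mean log2 CPM (prior count 2) of the lower peaks was subtracted from that of the higher peaks and the WT mean of that sex was set to 0. Scores were compared by exact two-sided permutation over all 924 arrangements of 6 against 6 animals. The SE of the share came from a jackknife over animals.

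Lists of genes were tested with camera of limma 3.58.1 on log2 CPM, over the peaks annotated to each list's genes, with an inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 23 lists within a comparison. The lists were striatal projection neuron (SPN) identity, dSPN, iSPN, striosome and matrix markers, activity-regulated genes, cAMP and dopamine signalling, ion channels, glutamate receptors and postsynaptic density, Polycomb-target developmental regulators, clustered protocadherins, mismatch repair and repeat instability, p53 targets, cholesterol biosynthesis, proteostasis and heat shock, interferon and innate immune genes, and markers of astrocytes, oligodendrocytes, OPC (oligodendrocyte precursor cells), microglia, endothelial cells and pericytes, cortical glutamatergic neurons and striatal interneurons. Counts of list peaks past the threshold were also adjusted over the list alone. Several lists share genes: SPN identity shares 11 genes with cAMP and dopamine signalling, and the oligodendrocyte and OPC lists share 3.

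Peaks named in the report followed a rule set before the data were examined. For Q140 vs WT, Msh3KO vs WT, Q140_Msh3KO vs Q140 and Q140_Msh3KO vs WT, it took the 8 higher and 8 lower peaks of largest fold change among called peaks of above-median abundance. These had a gene symbol, lay outside the 20 Mb windows and outside X and Y, had all 6 animals on 1 side of the other group's mean, and gave 1 peak per gene. It also took up to 4 peaks of smallest p from each list with a called peak and up to 2 from other lists, all Htt and Msh3 peaks, and Xist, Uty, Ddx3y, Kdm5d and Eif2s3y as a sex check. Any other named peak was chosen after its values were seen, and the text says so. A few peaks that the rule took are not reported here.

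The script for the peak test was tested on simulated data for Q140 vs WT with 146155 peaks drawn from the real means and library sizes. Of 100 peaks changed by 0.5 on the log2 scale, 5 were recovered, and of 100 changed by 1, 58 were recovered. Of 70 calls, 7 were false, which is 10% against the nominal 5%; this was a single run, and whether the error exceeds the threshold in general was not tested.

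Alternatives set before the data were examined were DESeq2 1.42.0 size factors, total counts and abundance-dependent offsets (loess span 0.3) in place of TMM; DESeq2 and limma-voom in place of edgeR; thresholds of 0.01 and 0.1; a fold limit of 0.5; other filters on low counts; no sex term; a replicate block; a random block for the number in the sample description; a surrogate variable from sva 3.50.0; the promoter share of counts as a covariate; only the groups compared; autosomes alone; no peaks near the targeted genes; and each library left out in turn. Leaving out repeat-annotated peaks, and leaving out Q140 F2 together with Q140_Msh3KO M1, were added after seeing the data. GC correction and motif scores need a genome sequence, which was not used here, and were not run. Chance was examined with 100 splits of the same libraries per comparison, fitted with limma.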

Results

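Chromatin accessibility was measured by ATAC-seq in NeuN-positive nuclei sorted from the striatum of 24 mice, 6 per genotype. WT animals were compared with Q140 animals, a knock-in model of Huntington's disease, with Msh3KO animals and with Q140_Msh3KO animals. Msh3 takes part in DNA mismatch repair and is needed for CAG repeats to grow in somatic cells, so the crossed animals ask what the expanded Htt allele does to chromatin when Msh3 is missing. Total counts in peaks were 7.61 ± 1.61 M in WT (SD, n = 6, range 5.13 to 9.26), 8.89 ± 1.66 M in Q140 (6.85 to 11.4), 8.05 ± 2.10 M in Msh3KO (4.37 to 9.87) and 8.08 ± 2.16 M in Q140_Msh3KO (5.82 to 11.7), where M is mega.

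The targeted genes were examined first. The promoter peak of Htt (huntingtin; chromosome 5, 34760964 to 34762717, GRCm38, as for all positions below) held 43.7 ± 6.17 CPM in WT, 43.2 ± 4.84 in Q140, 44.9 ± 7.60 in Msh3KO and 44.2 ± 3.69 in Q140_Msh3KO. Its log2 fold change in Q140 vs WT was -0.02 ± 0.11 (SE, adjusted p = 0.957). Peaks in Htt introns at 34772718 and 34773667 gave -0.16 ± 0.17 and -0.63 ± 0.25, neither past the threshold. The promoter peak of Msh3 (chromosome 13, 92354380 to 92355482) held 70.3 ± 9.46 CPM in WT and 70.7 ± 7.66 in Msh3KO, with a log2 fold change of 0.01 ± 0.10. Q140 animals held 68.4 ± 7.59 CPM there and Q140_Msh3KO animals 66.3 ± 4.90. ATAC-seq of these peaks measures neither the repeat length nor the transcript, so neither promoter checks the genotype. Signal inside Msh3 did differ by genotype, as given with the Msh3KO comparison.

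Sex-linked peaks matched the sexes given for the animals, with 1 library standing apart. Over the promoter of Uty, a Y-linked histone demethylase, females held 0 to 1 counts and males 36 to 84. At the promoter of Xist, the RNA that silences one X in females (chromosome X, 103483184 to 103483459), females held 4 to 44 counts and males 1 to 5. Q140 F2 held 1 count over Uty, Ddx3y, Kdm5d and Eif2s3y together, as a female does. Its share of counts on X was 1.47%, against 1.72% to 1.94% in the other females and 1.49% to 1.59% in males. In Q140_Msh3KO M1 the 10 highest peaks took 12.7% of counts, against 3.32% to 4.74% in the other animals of that genotype. Both libraries were kept, and each count of peaks below is also given without them, a choice made after seeing the data. The first principal component of log2 CPM held 19.7% of the variance and varied within genotypes, with SD of 49.2 to 94.6. Its Pearson r with the promoter share of counts was 0.405 (permutation p = 0.0497, n = 24). The second principal component, with 12.7% of the variance, ordered the genotypes. Its scores were -49.8 ± 14.7 in WT, -35.7 ± 8.45 in Msh3KO, 14.1 ± 19.2 in Q140_Msh3KO and 71.3 ± 12.5 in Q140 (SD, n = 6).

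Q140 vs WT asks what the expanded Htt allele does to accessibility. It changed 15066 of 146155 tested peaks, 6142 higher and 8924 lower in Q140. With scaling by total counts the split was 7488 higher and 7999 lower. The largest gain among peaks named by the rule was intergenic, at chromosome 4, 79271921 to 79272709, with A430085M09Rik as the nearest gene. It rose by 2.61 ± 0.19 on the log2 scale (SE, adjusted p = 4.6e-12), from 1.74 ± 0.462 to 10.6 ± 2.77 CPM (SD, n = 6). A peak near Cbx8, a chromobox subunit of the Polycomb repressive complex PRC1 (chromosome 11, 119053202 to 119054036), rose by 2.12 ± 0.17, from 7.24 ± 2.18 to 30.7 ± 4.28 CPM. The largest loss lay near B230110C06Rik (chromosome 14, 15171530 to 15171972), at -2.50 ± 0.30. The promoter of Serpina3g, a serine protease inhibitor gene (chromosome 12, 104235249 to 104235766), fell from 8.12 to 2.02 CPM (adjusted p = 7.7e-10). The other 6 higher peaks lay near Slitrk6 at 2.26 ± 0.21, Prelid2, Adam29, Dipk2a, 4930529K09Rik and 1700015G11Rik, the last at 1.91 ± 0.19. The other lower peaks lay near Fam240b at -2.48 ± 0.31, 2410141K09Rik, Olfr577, Gm20740, Rngtt and Lrrc4c, the last at -1.91 ± 0.22.

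Called peaks of genes that define striatal projection neurons were more often lower than higher. Of 864 peaks annotated to 34 SPN identity genes, 99 fell, 15 rose and 750 did not pass the test (107 lower and 17 higher adjusted over the list alone). The promoter of Ryr1, a calcium release channel of the endoplasmic reticulum, fell by 1.19 ± 0.15. Peaks of Rarb, a retinoic acid receptor, Penk, the enkephalin precursor, and Itpr1, an inositol trisphosphate receptor, gave -1.10 ± 0.14, -1.15 ± 0.15 and -1.18 ± 0.16. The list as a whole was lower by camera (median -0.15, adjusted p = 6.8e-04), a call lost at adjusted p = 0.591 with an estimated correlation and at 0.798 with promoter peaks only. The mean per animal over the list did not pass (exact permutation test, adjusted p = 0.156), and WT F3 stood apart at 0.61, with the other WT animals at 0.37 to 0.44. Of 497 peaks of cAMP and dopamine signalling genes, 54 fell and 10 rose (55 and 10 adjusted over the list alone). Examples are Pde7b, a cAMP phosphodiesterase, at -1.17 ± 0.17, Gnb5, a G protein subunit, at -0.94 ± 0.16, Rgs4, a regulator of G protein signalling, at -0.79 ± 0.14, and Adcy5, the main striatal adenylyl cyclase, at -0.66 ± 0.12. The adjusted p of this list was 0.0047, and adjusted p = 0.591 with an estimated correlation and 0.960 with promoter peaks only. Its mean per animal did not pass (exact permutation test, adjusted p = 0.199), and Q140 M3 stood apart at 0.58, with the other Q140 animals at 0.28 to 0.39.

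Called peaks of Polycomb-target developmental regulators were more often higher than lower. Of 738 peaks annotated to 112 genes, 60 rose and 15 fell (59 and 15 adjusted over the list alone). An intronic peak of Tbx5, a cardiac and limb transcription factor (chromosome 5, 119844848 to 119845621), rose by 1.81 ± 0.17, from 4.92 to 17.6 CPM. The promoter of Onecut1, a homeobox factor (chromosome 9, 74861498 to 74862162), rose by 1.60 ± 0.16, from 3.89 ± 0.403 to 11.8 ± 1.56 CPM. Peaks near Pax6 and Hoxc8, both homeobox genes, rose by 1.63 ± 0.21 and 1.25 ± 0.15. The list was higher by camera (adjusted p = 0.0014), a call lost at adjusted p = 0.576 with an estimated correlation. Its mean per animal did not pass (exact permutation test, adjusted p = 0.0830, 0.0108 before adjustment). Clustered protocadherins, cell surface proteins that give each neuron its identity, fell at 7 of 59 peaks and rose at 0 (9 lower adjusted over the list alone). Pcdhga4 gave -1.23 ± 0.13 and Pcdhgb5 -0.78. The adjusted p was 0.0267, and adjusted p = 0.232 with an estimated correlation, and 0.0830 for the mean per animal (exact permutation test, 0.0087 before adjustment).

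The remaining lists did not pass the threshold as lists, although each held called peaks. Among dSPN markers 7 peaks rose and 5 fell (6 and 4 adjusted over the list alone, adjusted p = 0.773), with Tac1, the substance P precursor, at 1.09 ± 0.17 and Drd1, the D1 dopamine receptor, at -0.59 ± 0.14. Among iSPN markers 4 rose and 14 fell (6 and 14, adjusted p = 0.30), with the kainate receptor gene Grik3 at -1.23. Striosome markers had 9 higher and 6 lower peaks (9 and 5, adjusted p = 0.476), with Bach2 at 1.81 ± 0.24. Matrix markers had 10 higher and 9 lower (15 and 10, adjusted p = 0.195), with Calb1, the calcium buffer calbindin, at 1.22 and the synaptic vesicle gene Sv2b at -1.78 ± 0.23. Activity-regulated genes had 12 higher and 24 lower (12 and 25, adjusted p = 0.704), among them Egr4 at -1.32 and Bdnf, a neurotrophin, at 1.04 ± 0.16. Ion channels had 30 higher and 73 lower (30 and 77, adjusted p = 0.195), with the potassium channels Kcna4 and Kcnd2 at 1.54 ± 0.17 and 1.42. Glutamate receptor and postsynaptic genes had 46 higher and 90 lower (52 and 98, adjusted p = 0.195), with the metabotropic receptor Grm7 at 1.63 ± 0.20 and the adhesion protein Nlgn1 at -1.40 ± 0.17. Mismatch repair and repeat instability genes had 2 higher and 8 lower (1 and 7, adjusted p = 0.830), with Hdac2, a histone deacetylase, at -1.17 ± 0.15.

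Of p53 targets 4 peaks rose and 6 fell (4 and 5, adjusted p = 0.830), with Ccng1 at 0.98; their median of -0.02 and mean of -0.01 lay below 0 while camera pointed up. Cholesterol biosynthesis genes had 2 higher and 10 lower peaks (2 and 10, adjusted p = 0.195), with Srebf2, the master regulator of the pathway, at -0.66. Proteostasis genes had 4 of each (4 and 3, adjusted p = 0.30), and interferon and innate immune genes 2 of each (2 and 2, adjusted p = 0.476; median -0.01, mean 0.01). Markers of other cells a NeuN sort could let through were tested too. Astrocyte markers had 6 higher and 14 lower peaks (7 and 19, adjusted p = 0.153), with the bicarbonate transporter Slc4a4 at -0.94 and the water channel Aqp4 up from 3.69 ± 1.11 to 8.61 ± 2.35 CPM (SD, n = 6). Oligodendrocyte markers had 4 higher and 5 lower (3 and 5, adjusted p = 0.888; median 0.01, mean -0.01), OPC markers 0 and 2 (0 and 2, adjusted p = 0.830; median 0.04, mean -0.01) and microglia markers 0 and 4 (0 and 4, adjusted p = 0.476). Endothelial and pericyte markers had 6 higher and 3 lower (6 and 3, adjusted p = 0.195). Cortical glutamatergic markers had 14 higher and 9 lower (18 and 10, adjusted p = 0.0882), with Rorb at -1.19. Striatal interneuron markers had 14 and 10 (14 and 9, adjusted p = 0.413), with Kit, a receptor tyrosine kinase, up from 5.42 ± 1.04 to 12.6 ± 2.71 CPM and Pvalb, parvalbumin, down from 4.27 ± 0.817 to 2.16 ± 0.551. Of these lists the oligodendrocyte and OPC lists share 3 genes, and the Polycomb list shares 3 with the cortical, 2 with the interneuron and 1 with the oligodendrocyte list. The cortical list shares 1 gene each with the matrix and activity lists, and the astrocyte, microglia and endothelial lists share 0.

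Changed peaks lay away from promoters. Promoter peaks made up 190 of the 6142 higher and 149 of the 8924 lower peaks, against 6.96% of tested peaks (Fisher's exact test, odds ratios 0.416 and 0.216, p = 2.1e-41 and 1.7e-125). Among higher peaks the odds ratio was 0.642 with scaling by total counts. Intergenic peaks were over-represented among both, with odds ratios of 1.75 and 1.24. The median distance to the nearest start was 57.3 kb for higher and 35.0 kb for lower peaks, against 28.8 kb for tested peaks. DESeq2 called 13657 peaks and limma-voom 17461, and 13024 were called without Q140 F2 and Q140_Msh3KO M1. Near Htt the share of called peaks did not differ from that of other autosomal peaks (284 of 2656, odds ratio 1.04, Fisher's exact p = 0.498), and near Msh3 it was higher (256 of 2026, odds ratio 1.26, p = 8.1e-04).

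**Figure D1:**
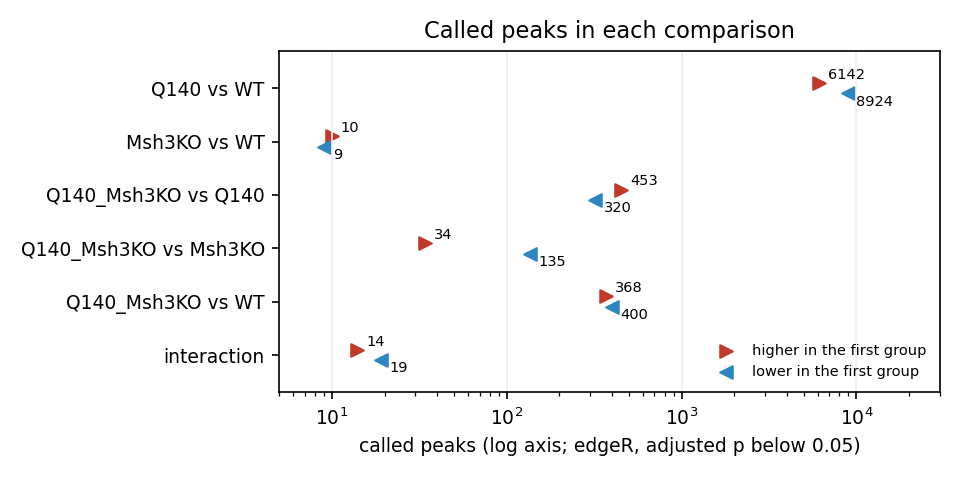
Number of peaks past an adjusted p of 0.05 in each comparison of genotypes and in the interaction, on a log axis, with peaks higher (red) and lower (blue) in the first group. Q140 vs WT gave 6142 higher and 8924 lower peaks, and Msh3KO vs WT gave 10 and 9.

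Msh3KO vs WT measures the loss of Msh3 on a wild-type Htt background. Of 146155 peaks, 19 changed, 10 higher and 9 lower in Msh3KO. All but 1 of them lay within 20 Mb of Msh3 on chromosome 13, where 18 of 2026 tested peaks changed against 0 of 138370 other autosomal peaks outside both windows (Fisher's exact p = 6.8e-34). The called peaks below are named after their values were seen. The largest change was at Gm4814 (93075857 to 93076284), at -2.57 ± 0.18. An intronic peak of Sv2c, a synaptic vesicle protein (96023633 to 96024453), rose by 1.74 ± 0.13, and a further peak at Sv2c by 1.06 ± 0.20. Both Iqgap2 peaks fell, by 1.36 ± 0.15 and 1.30 ± 0.12. Peaks near F2rl2, Zfp366, Map1b and 6430562O15Rik were lower, and peaks near Tmem174 and Cartpt were higher.

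The gene body of Msh3 itself was more accessible. All 24 tested peaks inside it were higher in Msh3KO, at a median of 0.77, and 4 of them passed the threshold. In Q140_Msh3KO vs Q140 all 24 were higher as well, at a median of 0.81 with 9 called, and in Q140 vs WT the median was -0.08. Within 200 kb on either side the medians were -0.06 over 5 peaks and 0.03 over 14 in Msh3KO vs WT, and 0.28 and 0.02 in Q140_Msh3KO vs Q140. On the higher coordinate side of Msh3, 14 of 1356 tested peaks changed, the farthest 7.54 Mb from the promoter of Msh3, and on the lower side 0 of 645. The single call elsewhere was the promoter of Pgk1, the X-linked phosphoglycerate kinase (chromosome X, 106186569 to 106187398), which rose by 1.36 ± 0.12 (adjusted p = 2.4e-10), from 23.7 to 61.0 CPM. A peak in an intron of Pgk1 gave 0.16 ± 0.27. Of the 23 lists, mismatch repair and repeat instability passed the threshold (4 peaks higher, 0 lower; 14 and 0 adjusted over the list alone; adjusted p = 6.1e-04, and adjusted p = 0.0017 with an estimated correlation). Without the 20 Mb windows its adjusted p was 0.952. At an unadjusted p of 0.05, 4875 peaks were counted where chance gives 7308. DESeq2 called 22 and limma-voom 23 peaks, and 18 were called without Q140 F2 and Q140_Msh3KO M1. With scaling by total counts the split was 7 higher and 10 lower.

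**Figure D2:**
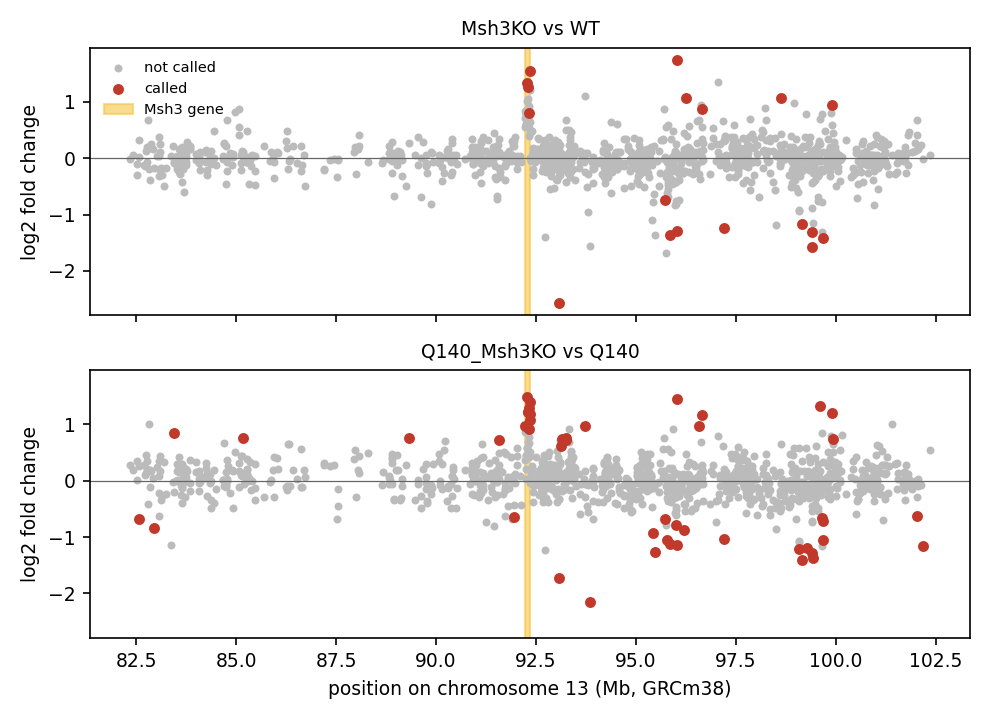
Log2 fold change of each tested peak within 10 Mb of Msh3 against its position on chromosome 13, for Msh3KO vs WT (top) and Q140_Msh3KO vs Q140 (bottom), with called peaks in red and the gene in yellow. Called peaks in the top panel lay inside Msh3 or at higher coordinates.

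Q140_Msh3KO vs Q140 asks what the loss of Msh3 does in animals with the expanded allele. It changed 773 peaks, 453 higher and 320 lower in Q140_Msh3KO, with 235 and 255 without Q140 M1 and 183 and 198 without Q140 M2. The largest loss among peaks named by the rule was in an intron near Gm26688 (chromosome 13, 40722641 to 40723512), at -1.58 ± 0.13 (adjusted p = 1.6e-10). The peak near Cbx8 that had risen in Q140 fell by 1.45 ± 0.16, to 11.5 ± 3.72 CPM (SD, n = 6). The Onecut1 promoter fell by 1.42 ± 0.16 and the peak 9.07 kb from Hoxc8 (chromosome 15, 102999076 to 103000139) by 1.41 ± 0.15, and the Tbx5 intron peak by 1.15 ± 0.16. The other lower peaks named by the rule lay near Msc, Edem1 and Gm20554, at -1.30 to -1.23. Among higher peaks, the one near Gm20740 rose by 1.49 ± 0.24, an intronic peak of Pphln1 (chromosome 15, 93443416 to 93444131) by 1.37 ± 0.15 and the Serpina3g promoter by 1.31 ± 0.19. Peaks near Nup160, a nuclear pore protein, and Cdh9 and Cdh11, both cadherins, rose by 1.44 ± 0.21, 1.42 ± 0.22 and 1.34 ± 0.20, and one near Gm36536 by 1.28 ± 0.19. The peak near B230110C06Rik gave 1.43 ± 0.34 (adjusted p = 0.0478), a call that ended in 17 of the 24 fits without 1 library, at adjusted p of 0.0526 to 0.123.

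Called peaks of Polycomb-target developmental regulators were all lower. Of their 738 peaks 26 fell, at 17 genes, and 0 rose (52 and 1 adjusted over the list alone; median -0.13). Beside Onecut1, Hoxc8 and Tbx5, the 5′ UTR peak of Cdkn2b, a cell cycle inhibitor, fell by 0.92 ± 0.15. The list's adjusted p was 2.8e-09, and adjusted p = 0.113 with an estimated correlation and 0.0556 by fry. Of the 3 lists that had fallen in Q140, 2 were higher, on few called peaks, and clustered protocadherins did not pass (adjusted p = 0.840). The means per animal of the 2 did not pass (exact permutation tests, adjusted p = 0.331 for SPN identity and 0.308 for cAMP and dopamine signalling). SPN identity had 4 higher and 0 lower of 864 peaks (6 and 0 adjusted over the list alone; adjusted p = 0.0040, and adjusted p = 0.526 with an estimated correlation). These were Homer1, a postsynaptic scaffold gene inside the 20 Mb window of Msh3, at 0.73, Itpr1 at 0.76, Arpp21 at 0.68 and Rarb at 0.65. Each lost its call when single libraries were left out, Homer1 in 3 of the 24 fits, Itpr1 in 5, and Arpp21 and Rarb in 7. cAMP and dopamine signalling had 1 called peak, at Pde7b, at 0.79 ± 0.18. The Pde7b call was lost without Q140 F1, F3 or M2 or Q140_Msh3KO F1, M1 or M2, at adjusted p of 0.0530 to 0.0854. This list's adjusted p was 0.0028, and adjusted p = 0.463 with an estimated correlation. Ion channels had 3 higher and 1 lower (3 and 1; adjusted p = 0.0222, and adjusted p = 0.294 with an estimated correlation), with Kcnk2, a potassium channel, at 0.87. Glutamate receptor and postsynaptic genes had 5 higher and 2 lower (5 and 2; adjusted p = 0.0273, and adjusted p = 0.294 with an estimated correlation), with Nlgn1 at 0.90 and the kainate receptor Grik2 at -1.14.

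Mismatch repair and repeat instability genes had 9 higher and 0 lower peaks (13 and 1; adjusted p = 0.0037, and adjusted p = 0.0073 with an estimated correlation). Among them was Hdac2 at 0.81 ± 0.15, and without the 20 Mb windows the adjusted p was 0.857. Cholesterol biosynthesis had 2 higher peaks (2 and 0; adjusted p = 0.0280, and adjusted p = 0.135 with an estimated correlation). Endothelial and pericyte markers were lower as a list with 0 called peaks (0 and 0; adjusted p = 0.0028, and adjusted p = 0.191 with an estimated correlation). Cortical glutamatergic markers were lower with 0 called peaks (3 and 3; adjusted p = 0.0190, and adjusted p = 0.0073 with an estimated correlation). By the mean per animal, the Polycomb, mismatch repair, endothelial and cortical lists passed (exact permutation tests, adjusted p = 0.0498 each). Cholesterol biosynthesis (0.0597), ion channels and glutamate receptors (0.308 each) did not. Before adjustment the 4 that passed had p of 0.0065, 0.0022, 0.0087 and 0.0043 in the same order. The mismatch repair mean includes peaks near Msh3 and was not tested without them. On the ion channel mean Q140 M3 stood apart at 0.05, with the other Q140 animals at -0.13 to -0.07. The other 14 lists did not pass by camera, and single peaks of theirs that passed include Pcdhga4 at 0.78 ± 0.14, Eya1 at 1.03, Epha4 at 0.96 and Kit at -0.74 ± 0.13. Near Msh3 51 of 2026 peaks changed (odds ratio 5.13, Fisher's exact p = 1.5e-19), and near Htt 15 of 2656 (odds ratio 1.13, p = 0.579). DESeq2 called 901 peaks and limma-voom 2021, and 199 were called without Q140 F2 and Q140_Msh3KO M1. Leaving out 1 library gave 490, 381 and 492 peaks without Q140 M1, M2 and M3, and 385, 383 and 378 without Q140_Msh3KO F2, M1 and M2.

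**Figure D3:**
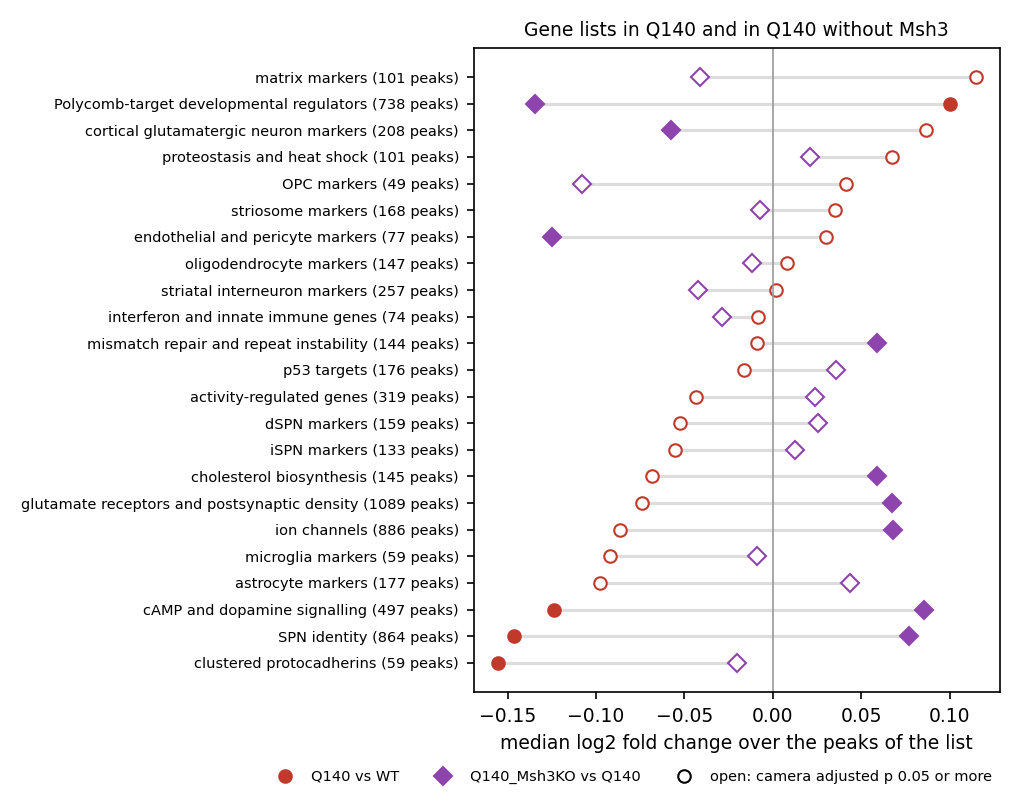
Median log2 fold change over the peaks of each gene list in Q140 vs WT (red circles) and Q140_Msh3KO vs Q140 (purple diamonds), filled where camera passed the threshold. SPN identity lay at -0.15 in Q140 vs WT and at 0.08 in Q140_Msh3KO vs Q140, and Polycomb-target regulators lay at 0.10 and -0.13.

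Of the 320 lower peaks, 290 were higher in Q140 vs WT, where independent calls would give 13.4, and 424 of the 453 higher peaks were lower in Q140 vs WT, where they would give 27.7. Both comparisons use the Q140 libraries, which alone turns fold changes against each other. The correlation across peaks was -0.67 against -0.48 with simulated unchanged groups, and the covariance -0.0606 against -0.0238. The simulated peaks were drawn independently, without other structure shared by libraries. With the Q140 libraries split between the comparisons the correlation was -0.37.

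Whether the Q140 effect differed with and without Msh3 was tested directly by the interaction, which called 33 peaks, 14 higher and 19 lower. The lower ones include Gm26688 at -1.39 ± 0.19 (adjusted p = 4.2e-04), the Onecut1 promoter at -1.63 ± 0.24 (0.0016), and the peaks near Hoxc8 at -1.47 ± 0.22, Cbx8 at -1.48 ± 0.25 and Tbx5 at -1.29 ± 0.25. Higher ones include Pphln1 at 1.32 ± 0.20, Nup35 at 1.38 ± 0.22, Serpina3g at 1.42 ± 0.25 and Nup160 at 1.53 ± 0.27. Nup35 was chosen after its values were seen. Among the lists, Polycomb targets were lower (0 higher and 4 lower peaks; 0 and 7 adjusted over the list alone; adjusted p = 1.5e-05, and adjusted p = 0.398 with an estimated correlation). SPN identity (adjusted p = 7.8e-04, and adjusted p = 0.473 with an estimated correlation) and cAMP and dopamine signalling (adjusted p = 0.0024, and adjusted p = 0.473 with an estimated correlation) were higher. Ion channels were higher too (adjusted p = 0.0309, and adjusted p = 0.399 with an estimated correlation), and endothelial markers were lower (adjusted p = 0.0035, and adjusted p = 0.398 with an estimated correlation). These last 4 lists held 0 called peaks by edgeR.

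DESeq2 called 99 and limma-voom 202 interaction peaks, 10696 had an unadjusted p under 0.05, and 9 were called without Q140 F2 and Q140_Msh3KO M1. Abundance-dependent offsets gave 174 higher and 89 lower. The count rested on single libraries. It was 8 without WT M1, 9 without WT M3, 62, 12 and 8 without Q140 F1, F2 and F3, and 21, 10 and 11 without Q140 M1, M2 and M3. It was 17 and 150 without Msh3KO F1 and F3, 15, 15 and 14 without Msh3KO M1, M2 and M3, 18 and 11 without Q140_Msh3KO F1 and F2, and 8, 12 and 67 without Q140_Msh3KO M1, M2 and M3.

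Q140_Msh3KO vs Msh3KO gives the Q140 effect in animals without Msh3, and shares no library with Q140 vs WT. It changed 169 peaks, 34 higher and 135 lower in Q140_Msh3KO. That balance rested on single libraries, with 28 higher and 30 lower without Msh3KO F3, 34 and 25 without Q140_Msh3KO F3, and 42 and 326 without Msh3KO F2. The peak near Dipk2a rose by 1.16 (adjusted p = 3.3e-04), that near A430085M09Rik by 1.14 (adjusted p = 0.0054) and that near Prelid2 by 0.96. The peaks near Fam240b, Olfr577 and Lrrc4c fell by 1.57, 1.12 and 1.03. These 6 were named by their change in Q140 vs WT. Of the 34 higher peaks 32 were also higher in Q140 vs WT (1.43 by chance), and of the 135 lower peaks 130 were also lower (8.24 by chance). Over all 6142 peaks higher in Q140 vs WT, 88.1% were higher here too, at a median of 0.25 against 0.74. Over the 8924 lower peaks 92.3% were lower, at -0.26 against -0.68. These peaks were chosen by their calls in Q140 vs WT, which can enlarge the 0.74 and -0.68 but not the 0.25 and -0.26. The correlation of fold changes across peaks was 0.43. Simulated unchanged groups gave 9.2e-04, but their peaks were drawn independently, so that value leaves out structure shared by libraries. By camera 0 of 23 lists passed the threshold with all peaks, 4 had an unadjusted p under 0.05, and fry called 0. Near Htt 10 of 2656 peaks changed (odds ratio 3.37, Fisher's exact p = 0.0012).

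DESeq2 called 225 and limma-voom 496 peaks in this comparison, and 183 were called without Q140 F2 and Q140_Msh3KO M1. Leaving out 1 library gave 112 without WT M1, 368, 58, 39, 73 and 49 without Msh3KO F2, F3, M1, M2 and M3, and 71, 59, 76 and 15 without Q140_Msh3KO F1, F3, M2 and M3.

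The size of the Q140 effect in each animal was measured with a score over peaks chosen in animals of the other sex. It was 0 ± 0.185 in WT (SD, n = 6), 2.15 ± 0.228 in Q140, 0.163 ± 0.173 in Msh3KO and 1.05 ± 0.296 in Q140_Msh3KO. Each Q140_Msh3KO animal, from 0.693 to 1.54, lay below each Q140 animal, from 1.73 to 2.37, and above each Msh3KO animal, the highest at 0.362. The exact two-sided permutation p was 0.0022, the smallest that 924 arrangements can give, for every pair of genotypes compared except Msh3KO vs WT. There the exact permutation p was 0.141 (0.0027 and 0.141 adjusted over 5 comparisons). With animals paired by sex and replicate number, an exact sign-flip permutation test gave p = 0.03125 (n = 6 pairs) for Msh3KO vs WT. The other comparisons gave the same value. Each Msh3KO animal lay above its WT partner. Whether loss of Msh3 alone raises the score therefore depends on the pairing and stays open. The difference between Q140_Msh3KO and Msh3KO was 41.2% of that between Q140 and WT (jackknife SE 7.54). Peaks higher in Q140 kept 41.7% of their effect and lower peaks 40.7%. Between the sexes' choices, 219 of 500 higher and 233 of 500 lower peaks were the same.

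**Figure D4:**
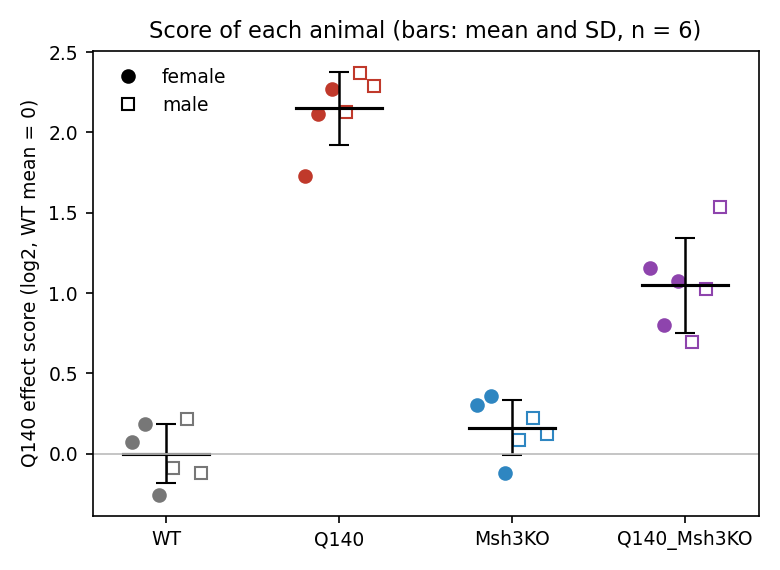
Q140 effect score of each animal in log2 units with the WT mean at 0, by genotype, with females as filled circles, males as open squares, and bars for mean and SD (n = 6). Q140_Msh3KO animals lay at 1.05 ± 0.296, between Q140 at 2.15 ± 0.228 and Msh3KO at 0.163 ± 0.173.

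Q140_Msh3KO vs WT shows what remained different from wild type in the crossed animals. It changed 768 peaks, 368 higher and 400 lower, with 287 and 155 without WT F3 and 197 and 154 without WT M1. The peak near A430085M09Rik rose by 1.70 ± 0.21 (adjusted p = 4.6e-06), to 5.67 ± 2.19 CPM against 10.6 ± 2.77 in Q140 (SD, n = 6). Peaks near Dipk2a, Prelid2 and Slitrk6 rose by 1.40 ± 0.17, 1.35 ± 0.19 and 1.30 ± 0.23. Other gains named by the rule lay near Kynu, an enzyme of tryptophan breakdown, at 1.27 ± 0.19, 4921533I20Rik, and Nmbr, the neuromedin B receptor, at 1.21 ± 0.20. The peak near 4930529K09Rik gave 1.27 ± 0.27, a call lost at adjusted p of 0.0518 to 0.0616 without WT F1, Q140_Msh3KO F1 or Q140_Msh3KO F2. The largest losses among peaks named by the rule, which lie outside the 20 Mb windows, were near Fam240b at -1.72 ± 0.29, Xkr5 at -1.26 ± 0.20, Mir429 and Shisa9, an AMPA receptor-associated protein, at -1.16 ± 0.16. Peaks near 1110038F14Rik, Uqcrb, Gm10654 and Nolc1 gave -1.12 to -1.08. Near Msh3, a peak at Polk, a translesion DNA polymerase, rose by 1.11 ± 0.22.

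Clustered protocadherins were lower as a list with 0 called peaks (0 and 0; adjusted p = 4.6e-04, and adjusted p = 0.0267 with an estimated correlation), and their mean per animal did not pass (exact permutation test, adjusted p = 0.133). Mismatch repair and repeat instability was higher with 7 higher peaks (10 and 3; adjusted p = 0.0423, and adjusted p = 0.0293 with an estimated correlation), and its adjusted p was 0.992 without the 20 Mb windows. SPN identity had 0 higher and 3 lower peaks (1 and 5) and Polycomb targets 1 and 0 (0 and 0), and neither list passed. Near Msh3 57 of 2026 peaks changed (odds ratio 5.92, Fisher's exact p = 2.0e-24) and near Htt 27 of 2656 (odds ratio 2.10, p = 6.4e-04). Called in the same direction in Q140 vs WT were 705 peaks, where independent calls give 39.9, and 3 were called in opposite directions. The WT libraries are shared here. The correlation was 0.71 against 0.52 with simulated unchanged groups, whose peaks were drawn independently. It was 0.40 with WT split, and the covariance was 0.0676 against 0.0268 in the simulation. DESeq2 called 907 and limma-voom 1377, and 915 were called without Q140 F2 and Q140_Msh3KO M1. Leaving out 1 library gave 442, 351 and 342 without WT F3, M1 and M3, and 352, 452 and 200 without Q140_Msh3KO F1, M2 and M3.

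Female vs male animals differed at 247 peaks, 141 higher and 106 lower in females. On X 137 of 2976 tested peaks were called and all 137 were higher in females. On Y 31 of 127 were called and all were lower. On autosomes 79 were called, 4 of them higher in females. The Xist promoter peak gave 2.75, and Ddx3y, a Y-linked RNA helicase, had 0 counts in every female. DESeq2 called 334 and limma-voom 249, and 365 were called without Q140 F2 and Q140_Msh3KO M1. Abundance-dependent offsets gave 249 higher and 116 lower. The Q140 effect did not detectably differ between sexes. By edgeR 0 peaks were called in the test of that difference, DESeq2 and limma-voom also called 0, and 0 were called without Q140 F2 and Q140_Msh3KO M1. At an unadjusted p of 0.05, 4806 peaks were counted where chance gives 7308.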

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

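The tests of the promoter share and of cortical against interneuron markers below were set before their results were seen. The tests of markers of all other cell types, of strain DNA, of neighbouring genes, of a Pgk1 cassette, of the sex and X content of Q140 F2, and of other splits of the libraries were chosen after.

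The Q140 effect was smaller in animals without Msh3. The test of that difference called 33 peaks, and over lists its adjusted p was 7.8e-04 for SPN identity, 0.00244 for cAMP and dopamine signalling, 0.0309 for ion channels, 1.5e-05 for Polycomb targets and 0.00349 for endothelial markers, each lost with an estimated correlation. The promoter share of counts, taken as a measure of library quality, was argued against as the whole cause. It was 21.2 ± 1.03% in Q140 and 21.5 ± 1.79% in Q140_Msh3KO (SD, n = 6), so adjusting for it could move the score difference little. After its trend within genotypes was removed, that difference was 1.08 (SD 0.280 and 0.272, exact permutation p = 0.0022, n = 6), against 1.10 before. Quality differences that this share does not carry were not tested. A smaller share of projection neurons among sorted Q140 nuclei could raise markers of other cell types. Cortical against interneuron markers did not decide (exact permutation p = 0.355). The differences of 7 such lists lay farther apart than in nearly all other arrangements of the animals (exact permutation p = 0.0022). They were 0.09 for cortical and -0.08 for astrocyte markers (exact permutation tests, adjusted p = 0.0830 each). This does not decide either, since a smaller share need not move every list alike and Q140 could change single lists. A smaller share of projection neurons therefore stays open. A change in the share of cortical-type nuclei stays open, and so does the biological explanation that the CAG repeat grows less without Msh3 and the effect with it, which may apply and was not tested, since no value here measures the repeat.

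Changes in Msh3KO vs WT lay beside Msh3. DNA of another strain carried along with the targeted allele is a candidate explanation: 15 of the 18 called peaks near Msh3 were also called, in the same direction, in Q140_Msh3KO vs Q140, which shares no library with the first comparison, and all 18 had the same sign. Loss of Msh3 acting on its neighbours predicts the same peaks, so the 2 cannot be told apart here; the farthest peak lay 7.54 Mb from the Msh3 promoter. The gain at the Pgk1 promoter may come from a targeting cassette with Pgk1 promoter and terminator sequence, since peaks at the start and end of Pgk1 rose by at least 1.29 in both comparisons while the tested peak between them gave 0.16 (SE 0.27); the end peak was not called in Msh3KO vs WT (adjusted p = 0.124). The allele's construction is not given in the sources used here.

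Q140 F2 had less X-linked signal than other females. A male animal taken for a female was argued against by 1 count over Uty, Ddx3y, Kdm5d and Eif2s3y, where male libraries held 152 to 303 and other females at most 3. A single X chromosome could account for it: the X share of counts was 1.47%, against 1.49% to 1.59% in males and 1.72% to 1.94% in other females. Its Xist count was 42, with at most 52 in males and at least 76 in other females. Loss of X from part of the cells was not tested, and no group of the design offers a biological explanation.

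Other libraries stood apart from their genotype by the ratio of the gap to the range among 6 animals. This occurred in 14 of 120 measures by genotype, and chance marks about 1 in 20. Q140_Msh3KO M1 was high in the share of counts in its 10 highest peaks (ratio 0.848) and in repeat-annotated peaks (0.664; 18.6% against 14.3% to 15.7%). WT F3 was high in the mean over SPN identity (0.683), ion channel (0.771) and glutamate receptor peaks (0.657) and low over interneuron markers (0.638). Q140 M3 was high over cAMP and dopamine signalling (0.642) and ion channels (0.653) and low over endothelial markers (0.640). Msh3KO F2 was low over striosome markers (0.703) and high over microglia markers (0.667). Q140_Msh3KO F3 was low over dSPN markers (0.704) and high over oligodendrocyte markers (0.632). Q140 F1 was low at the Htt promoter (0.630), with 34.5 CPM against 42.9 to 47.9.

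Counts of called peaks were set against 100 splits of the same libraries per comparison, the real one included. For Q140 vs WT only the real split gave as many (15099 by limma, highest other 3151). For Msh3KO vs WT 2 of 100 splits did (11 by limma, highest other 3389), and for Q140_Msh3KO vs Q140 2 (992, highest other 4764). As many came from 3 splits for Q140_Msh3KO vs Msh3KO (14, highest other 1835) and 2 for Q140_Msh3KO vs WT (1045, highest other 2203). The interaction had 4 (31, highest other 658) and female vs male 2 (254, highest other 10254). These shares were not adjusted over the comparisons, and the limma counts differ from the edgeR counts above. Outside Q140 vs WT some other split called more peaks than the real one, so this test does not exclude chance there. For the Q140 effect by sex the real count was 0, so every split gives as many (100 of 100, highest other 1109) and nothing is decided. Splits that call several times the real count point to a structure of the samples, as in every comparison here except Q140 vs WT and Q140_Msh3KO vs WT.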

How the results depend on the processing

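Leaving out repeat-annotated peaks, and leaving out Q140 F2 with Q140_Msh3KO M1, were chosen after seeing the data. Calls on the location of changed peaks were the same in every setting run, although the odds ratio of promoter peaks among higher peaks moved from 0.416 to 0.642 with total counts. The direction at Q140 peaks and the share of the Q140 effect kept (36.0% to 44.5% over other choices of peaks and animals) stayed within their limits. Of 186 named called peaks 0 reversed in any setting and 143 passed the threshold whichever 1 library was left out; 26 were no longer called without Q140 F2 and Q140_Msh3KO M1, 12 with the block on the description number and 7 with the promoter share as covariate. Counts of called peaks moved by over 1.5 times as follows, and the cause was not tested except where a threshold or a narrower set of peaks or animals sets it.

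At an adjusted p of 0.01 there were 8433 peaks for Q140 vs WT, 225 for Q140_Msh3KO vs Q140, 16 for Q140_Msh3KO vs Msh3KO, 178 for Q140_Msh3KO vs WT and 6 for the interaction. At 0.1 the last 4 gave 1612, 381, 1730 and 80. In the same order, abundance-dependent offsets gave 1641, 454, 1623 and 263, limma-voom 2021, 496, 1377 and 202, the more abundant peaks (over the median) 1396, 373, 1374 and 167, a surrogate variable 3421, 1755, 4079 and 1242, and no repeat-annotated peaks 1379, 314, 1239 and 165. The surrogate variable also gave 22612 for Q140 vs WT, 38 for Msh3KO vs WT and 654 for female vs male. The more abundant peaks gave 61 for female vs male, no repeats 95, and autosomes alone 75. For the interaction, total counts gave 61, DESeq2 99, the promoter share as covariate 78 and the block on the description number 61. For Q140_Msh3KO vs Msh3KO, only the groups compared gave 37 and the promoter share 441. Without 20 Mb around the targeted genes Msh3KO vs WT gave 1. Without Q140 F2 and Q140_Msh3KO M1, Q140_Msh3KO vs Q140 gave 199 and the interaction 9.

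Libraries of the same sex and replicate number in other genotypes deviated together only weakly, at a mean r of 0.0320 over 36 pairs (11 over 0.1), against -0.0165 for other numbers. Of 24 libraries, 13 were closest to their own number among the 3 of their sex. That is more than an even choice would give, and the excess was not tested. Pairing by number is therefore not excluded, and the main fit did not use it. The 10 pairs sharing a description number had a mean r of 0.140, against -0.00673 otherwise. As a random block that number had an estimated correlation of 0.162. The replicate block gave 55 interaction peaks and left 1 list for Q140_Msh3KO vs WT, since mismatch repair no longer passed (adjusted p = 0.0553). It moved no other count by over 1.5 times, and ended the calls of 3 named peaks.

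Leaving out 1 library at a time gave 11904 to 16024 peaks for Q140 vs WT, 14 to 21 for Msh3KO vs WT, 378 to 1104 for Q140_Msh3KO vs Q140, 15 to 368 for Q140_Msh3KO vs Msh3KO, 200 to 1078 for Q140_Msh3KO vs WT, 8 to 150 for the interaction, 197 to 350 for female vs male, 0 to 0 for the Q140 effect by sex, and 36.7% to 44.5% for the share kept.

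Lists past the threshold numbered 0 for Q140 vs WT with an estimated correlation and 2 with promoter peaks only (4 with all peaks); 0 for Msh3KO vs WT with promoter peaks or without the windows (1); and for Q140_Msh3KO vs Q140 2 with an estimated correlation, 3 by fry and 4 with promoter peaks (9). They numbered 3 for Q140_Msh3KO vs Msh3KO with promoter peaks (0), 1 for Q140_Msh3KO vs WT with total counts or without the windows (2), and for the interaction 0 with an estimated correlation, 0 by fry and 3 with promoter peaks (5). With promoter peaks the glutamate receptor and mismatch repair lists turned down in Q140_Msh3KO vs Q140, each at adjusted p = 0.768. Motif scores, the central 200 bases of peaks, GC correction and the replicate block with GC correction were not run. At a median of 28 counts per peak and library, 5 of 100 simulated changes of 0.5 were recovered for Q140 vs WT. That simulation gave 70 calls, where the real comparison gave 15066, and the adjustment is stricter when few peaks change. The recovery therefore does not give the power of the real comparison, and how often small changes were missed is not known.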

Other observations

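The tests of this part, on copies of Msh3, on the level of Polycomb promoters and on GATA repeats, were all chosen after the results were seen.

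In a small part of the genome, changed peaks of Q140 vs WT gathered in blocks. Among 2126 windows of 1 Mb with at least 20 tested peaks, 19 held more lower and 15 more higher peaks than independent peaks would give (adjusted p under 0.05). Neighbouring peaks can vary together across animals, which this test does not allow for, so its p-values are descriptive. The strongest lower window, chromosome 7 from 107000001 to 108000000, held 12 lower of 26 tested peaks around Syt9, a synaptotagmin, Ppfibp2 and Cyb5r2 (adjusted p = 2.4e-05). Another, on chromosome 17 from 8000001, held 30 lower of 172 around Pde10a, a phosphodiesterase abundant in striatal projection neurons, and one on chromosome 13 from 33000001 held 11 of 27 in a cluster of Serpinb genes. The strongest higher window, chromosome 3 from 147000001, held 12 higher of 28 around Ttll7 and Adgrl2 (adjusted p = 1.0e-06). On chromosome 2 from 116000001, 18 of 81 peaks were higher and 0 lower around Meis2, a homeobox gene, and on chromosome 9 from 94000001, 13 of 38 were higher around Slc9a9 and Dipk2a.

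Repeat families differed in direction. LINE peaks were rare among higher and lower peaks (odds ratios 0.366 and 0.509). SINE and LTR peaks were rare among higher (0.562 and 0.516) and common among lower peaks (confidence intervals 1.34 to 1.67 and 1.33 to 1.57). DNA transposons were common in both, at 2.21 and 1.52. A few peaks with a high median over all libraries were higher still in 1 library. A promoter peak of Crebzf (chromosome 7, 90441718 to 90442191) held 648480 counts in Q140_Msh3KO M1, with CPM 10.3 times the median of all libraries. A C repeat near Ddhd1 held 9.84 times the median in that library, and an intergenic peak near Col19a1 (chromosome 1, 24611579 to 24616147) 2.93 times the median in WT F1. In this order the medians were 8539, 903 and 9841 CPM.

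All 24 tested peaks inside Msh3 were higher without the gene's function, which extra copies of the whole gene could explain. Against this, the Msh3 promoter peak has an upper limit (95%) of 0.21, below the median of 0.77 inside the gene.

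Polycomb-target promoters in Q140_Msh3KO may lie below wild type rather than at it. Over 109 promoter peaks the mean per animal was lower than in WT by a log2 difference of -0.12 (SD 0.169 and 0.184, exact p = 0.251, n = 6), so this stays open. It was above WT in Q140 by 0.22 (exact p = 0.0216) and below Q140 in Q140_Msh3KO in 6 of 6 animals (difference -0.35, exact p = 0.0022).

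Some autosomal peaks higher in males may be reads from GATA-type repeats of the Y chromosome placed elsewhere. Of 43 tested autosomal peaks on such repeats 43, or 100%, were lower in females, at a median of -1.97, and 42 were called. Among 2635 other simple repeats 57.5% were lower (Fisher's exact p = 7.8e-11). A further 17 called lower peaks on those repeats and 16 on other autosomal peaks are left unexplained.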
